A study of Mus musculus with 9 samples.

How the data were processed

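RNA sequencing data of 9 libraries from in vitro mouse monocytes were used, 3 each of the conventional, intermediate and patrolling subsets named by the sample labels. Per the labels' protocols, RNA was extracted with RNAzol and libraries were made with the NEBNext Ultra II stranded mRNA kit. The deposited table holds estimated counts per gene, 1 column per library, which were made with kallisto 0.46.1 and the mm10 genome per the submitters' processing notes. The transcript annotation, the step from transcripts to genes, any filter and the strand setting are not given in the sources used here, so counts of genes that overlap others or lie antisense to them are uncertain. Between 25.6% and 27.5% of the values per library were not whole numbers, and values were rounded before testing.

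The table lists 46517 Ensembl gene IDs. Of these, 46005 matched a symbol of the GENCODE M21 annotation of GRCm38 once the version suffix was left aside, 512 did not match, and 118 shared a symbol with another ID. The coordinates and biotypes printed come from that annotation and are counted from 1. Totals ran from 18455008 to 29985563 estimated counts per library. Reads without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only. Where a subset had 0 counts of a gene, the fold is a lower bound from a floor of 3 counts over the subset, and for 1 to 3 counts the ratio is given with an exact 95% counting interval.

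Genes were kept with edgeR's filterByExpr by subset, which left 14059 genes, and libraries were scaled by TMM. All 9 libraries were fitted together with subset as the term in edgeR 4.0.16 (quasi-likelihood F test with robust fitting, R 4.3.3). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 fold changes are given with standard errors, and CPM (counts scaled to the library size after TMM) as mean ± SD of 3 libraries. Of the 3 pairwise comparisons, each was taken as a contrast of this fit, and an F test on both coefficients asked whether any subset differed. Principal components were computed on log2 CPM with a prior count of 2.

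The 18 gene lists were fixed from general knowledge, not from these libraries. They held conventional and patrolling monocyte, MHC class II, macrophage, dendritic cell, Notch pathway, cell cycle, interferon-stimulated, inflammatory cytokine, chemokine receptor and integrin, sterol and LXR, and lysosome genes. Granulocyte and progenitor, stromal, lymphoid, and erythroid to eosinophil lists looked for other cell types. Those of immediate early and heat shock and of mitochondrial genes looked at sample quality. Sizes count tested genes, of 14 Notch, 16 lymphoid and 18 erythroid to eosinophil genes listed. Lists were tested against all other genes with camera of limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 between genes, two-sided, and Benjamini-Hochberg adjustment over the 18 lists and 3 contrasts. The test was repeated with the correlation estimated, which called no list. Members were also counted after adjustment over the list alone.

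The named genes follow a rule. It takes a set of core genes, the 2 called members with the largest change and no overlap between subsets in each list of monocyte biology (or its most abundant member where there is none), the most abundant member of each other list, and the 5 highest and 5 lowest changes among called genes with a mean of at least 20 CPM over all 9 libraries and no overlap, leaving out unnamed gene models. Some genes that it takes are not reported here. Genes outside it are described as named after the values were seen. The lists, the rule, the edgeR and camera tests and their alternatives were chosen before the data were examined. The fit to libraries 1 and 2 alone was added after libraries 0 were seen to lie apart, and the tests of explanations and of other splits of the libraries were written after the result was seen. That fit has 2 libraries per subset. Log2 CPM of libraries 1 and 2 correlated at 0.987 in cMo, 0.986 in intMo and 0.99 in pMo. Within subsets, correlations with library 0 were 0.951 to 0.975. The spread in that fit is therefore smaller, which alone can add calls, and its calls are not independent of the main fit.

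The steps were tested on simulated data drawn from the real means and library sizes of the 14059 genes, with 200 genes changed per contrast. For intMo against cMo, 26% of genes changed by a log2 of 1 and 71% of those changed by 2 were recovered, with 3 unchanged genes among 100 calls. For pMo against intMo, the shares were 23% and 73%, with 4 unchanged genes among 100 calls, and for pMo against cMo they were 25% and 69%, with 3 among 97. In simulated lists the changed list was called (camera adjusted p = 8.52e-22) and 0 of 17 unchanged lists were called by camera. Each gene was drawn on its own, so this did not test camera on lists whose genes move together.

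The alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, no filter on low counts, a filter at a CPM of at least 1 in 3 libraries, the replicate number as a block, only the 6 libraries compared, a test against a log2 change of 1, and each library left out in turn. For lists they also included the estimated correlation and a prior count of 0.5. The labels give no batch or date, and nothing says what the replicate numbers stand for, so the fit had no block. The deviations of pMo and intMo libraries with the same number from their subset means correlated at 0.59, 0.3 and 0.27 for numbers 0, 1 and 2, all over 0.1, so the numbers were taken to pair these subsets. This pairing comes from the data and not from the labels, and libraries 1 and 2 crossed correlated at 0.4 and 0.28, so it sets library 0 apart more than 1 from 2. Values with the replicate number as a block are given for this comparison where they changed a call.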

Results

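RNA sequencing libraries were made from primary monocytes of wild-type C57BL/6 mice that were grown in vitro. The sample labels name 3 subsets with 3 libraries each, numbered 0, 1 and 2, which are conventional monocytes (cMo), intermediate monocytes (intMo) and patrolling monocytes (pMo). The series title places the patrolling cells in cultures of bone marrow with OP9-DLL1 cells, a stromal line that carries the Notch ligand Delta-like 1. The series description names the conventional subset where the sample labels name the patrolling subset. How the subsets were sorted is not given in the sources used here. The labels do not say whether the libraries of a subset come from separate cultures or animals. The edgeR and DESeq2 p-values therefore measure only the spread between these libraries. Those of camera set the genes of a list against all other genes, taken as nearly independent at the preset correlation. The blood and bone marrow counterparts and the macrophages named in the title were not analysed here.

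The total estimated counts were 27097593, 27197196 and 27760266 in cMo libraries 0, 1 and 2, in that order. They were 18455008, 23287482 and 29583014 in intMo and 25127133, 29985563 and 23725441 in pMo. Of 46517 genes in the table, 14059 had enough counts to be tested. On the first principal component, which held 57.8% of the variance, the cMo libraries lay between -102.8 and -79.1 and those of intMo and pMo between 18.9 and 67.4. On the second component, with 13.5% of the variance, intMo library 0 lay at 63.7 and the other two intMo libraries at 14.6 and 17.7, while pMo library 0 lay at -9 and the other two pMo libraries at -41.1 and -47.6.

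**Figure D1:**
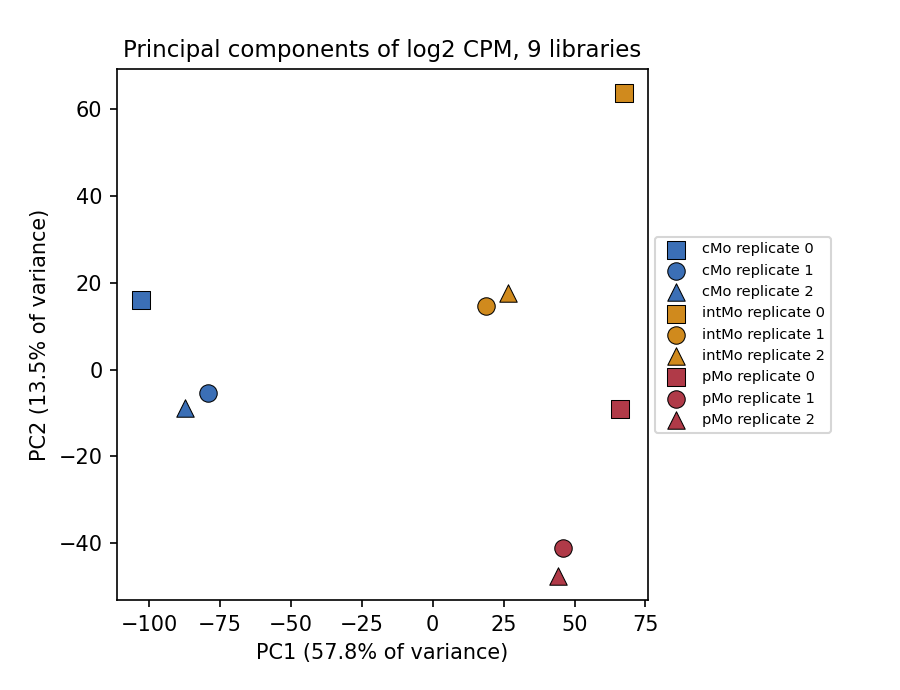
The 9 libraries on the first 2 principal components of log2 CPM (counts scaled to library size), with 1 point per library and the subset shown by colour. The cMo libraries lie apart on the first component, and library 0 of each subset lies away from the others of its subset.

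The 11 core genes below were fixed in advance and are all annotated as protein coding in GRCm38. Those for surface markers of conventional monocytes were Ly6c2 (ENSMUSG00000022584.13, chromosome 15, 75108158 to 75111970) and Ccr2 (ENSMUSG00000049103.12, chromosome 9, 124101950 to 124113557). Those linked to patrolling monocytes were Spn (ENSMUSG00000051457.6, chromosome 7, 127132232 to 127137823), Cx3cr1 (ENSMUSG00000052336.6, chromosome 9, 119901616 to 120069879) and Itgax (ENSMUSG00000030789.8, chromosome 7, 128129547 to 128150657). Nr4a1 (ENSMUSG00000023034.6, chromosome 15, 101254269 to 101274795) and Treml4 (ENSMUSG00000051682.14, chromosome 17, 48264295 to 48275360) belonged to the same group. The remaining genes of wider myeloid use were Csf1r (ENSMUSG00000024621.14, chromosome 18, 61100598 to 61132149) and Itgam (ENSMUSG00000030786.17, chromosome 7, 128062640 to 128118491). Adgre1 (ENSMUSG00000004730.13, chromosome 17, 57358691 to 57483527) and H2-Ab1 (ENSMUSG00000073421.5, chromosome 17, 34257689 to 34269419) were also included. Ly6c2, Ly6i, Ear2, the Bcl2a1 genes and the MHC class II genes have close paralogs, so the division of reads among the copies is uncertain.

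**Figure D2:**
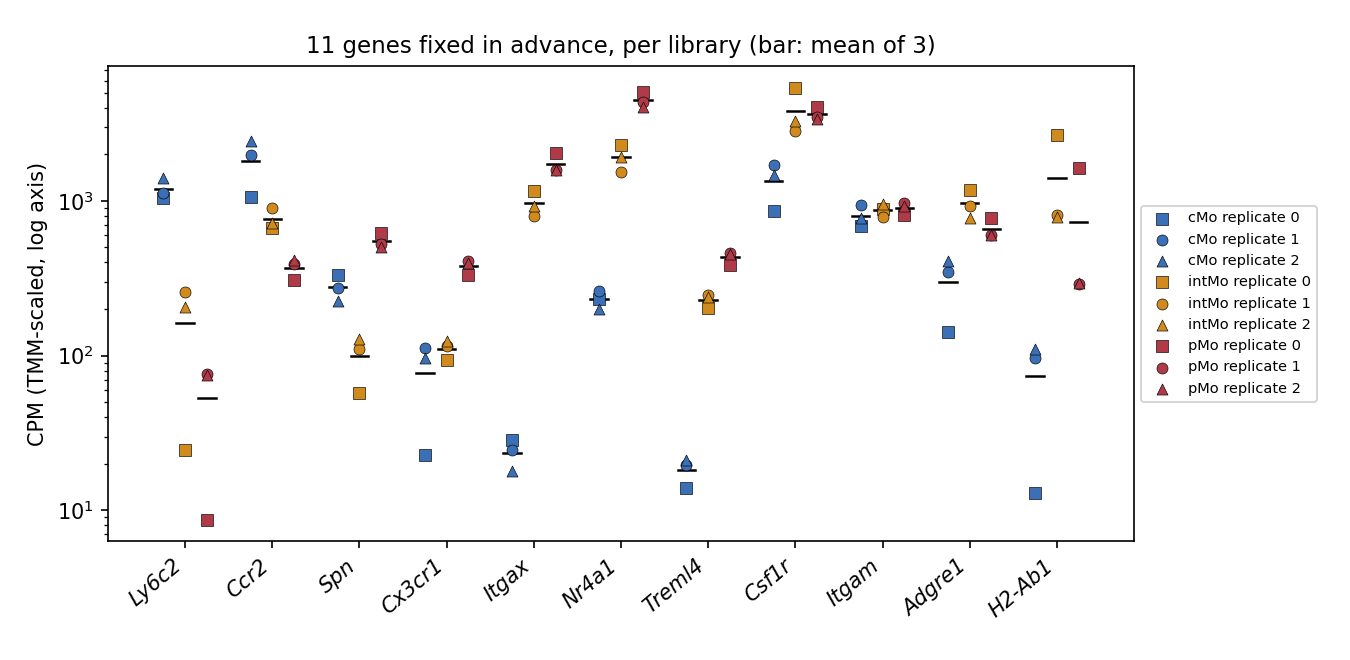
CPM of the 11 core genes in each library on a log axis, with 1 point per library and the mean of each subset. Mean Itgax was 23.6 CPM in cMo, 963 CPM in intMo and 1727 CPM in pMo, and mean Nr4a1 was 232, 1923 and 4490 CPM.

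Intermediate monocytes were first compared with conventional monocytes, which asks what distinguishes them from the conventional subset. Ly6c2, the surface glycoprotein that marks conventional monocytes, fell from 1190 ± 189 to 163 ± 122 CPM (mean ± SD, n = 3 libraries per subset), a log2 fold change of -2.87 ± 0.90 (SE, edgeR adjusted p = 0.0466). Ccr2, the chemokine receptor that lets monocytes leave the marrow, fell from 1818 ± 694 to 761 ± 123 CPM (log2 -1.26 ± 0.28, edgeR adjusted p = 0.0117). Nr4a1, the nuclear receptor that patrolling monocytes require, rose from 232 ± 29.7 to 1923 ± 386 CPM (log2 3.05 ± 0.19, edgeR adjusted p = 2.2e-05). Itgax, the integrin subunit CD11c, rose from 23.6 ± 5.16 to 963 ± 178 CPM (log2 5.35 ± 0.24, edgeR adjusted p = 6.64e-06), and Treml4, a receptor of patrolling monocytes that binds dying cells, rose from 18.2 ± 3.87 to 230 ± 23.6 CPM (log2 3.66 ± 0.19, edgeR adjusted p = 9.02e-06). Each of these genes had all 3 libraries of one subset above all 3 of the other, an outcome that chance gives for 10% of genes. The edgeR call of Ly6c2 was lost on leaving out any 1 of 8 libraries, all but pMo 0, with adjusted p up to 0.101. Nr4a1 is also an immediate early gene, and immediate early and heat shock genes rose by a mean log2 of 2.52 in this contrast. A response to handling was not tested for Nr4a1 here.

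Spn, which encodes the sialoglycoprotein CD43 of patrolling monocytes, moved the other way and fell from 277 ± 52.9 to 99.2 ± 37.5 CPM (log2 -1.48 ± 0.28, edgeR adjusted p = 0.00587). Cx3cr1, the fractalkine receptor, was not called between 77.3 ± 47.7 CPM in cMo and 111 ± 15.7 CPM in intMo (log2 0.52 ± 0.46, edgeR adjusted p = 0.442). Itgam, the integrin subunit CD11b of myeloid cells, was not called either (799 ± 124 and 873 ± 86.2 CPM, log2 0.13 ± 0.15, edgeR adjusted p = 0.565). Csf1r, the receptor for the growth factor CSF1, rose from 1347 ± 434 to 3836 ± 1373 CPM (log2 1.51 ± 0.29, edgeR adjusted p = 0.00676). Adgre1, a surface receptor of macrophages, rose from 299 ± 138 to 964 ± 200 CPM (log2 1.69 ± 0.35, edgeR adjusted p = 0.00867). H2-Ab1, an MHC class II beta chain, rose from 73.5 ± 53 to 1416 ± 1072 CPM (log2 4.27 ± 1.03, edgeR adjusted p = 0.0173). The log2 change of Csf1r was 0.95 with libraries 1 and 2 alone, a choice made after the data were seen.

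Of 14 conventional monocyte genes, 11 fell, none rose and 3 were not called. Adjusted over the list alone, 12 fell. Fn1, the matrix protein fibronectin, fell by 3.18 ± 0.57 on the log2 scale (edgeR adjusted p = 0.00474). The list was lower by camera (adjusted p = 2.38e-05, and adjusted p = 0.422 with an estimated correlation). Of 24 patrolling monocyte genes, 18 rose, 3 fell and 3 were not called, and 18 rose and 4 fell when adjusted over the list alone. Ace, the angiotensin-converting enzyme of patrolling monocytes, rose by 5.90 ± 0.55 (log2, edgeR adjusted p = 0.000218). The members that fell were Spn, Cebpb, a transcription factor of monocyte survival (log2 -0.51 ± 0.16), and Klf2, a factor of leukocyte quiescence (log2 -1.17 ± 0.22), of which the last pair was named after the values were seen. The Cebpb call (edgeR adjusted p = 0.0474) was lost without any 1 of the 8 libraries other than pMo 0, at up to 0.148, and with upper quartile scaling (0.0699) or a filter at 1 CPM (0.0606). Camera called the list higher (adjusted p = 1.16e-08, and 0.266 with an estimated correlation). Lists named for a subset share members, with 4 of the patrolling and 2 of the conventional genes also in other lists.

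MHC class II antigen presentation genes rose in 13 of 14 cases, with 1 not called and 14 higher when adjusted over the list alone. H2-Eb1, another class II beta chain, rose by 4.47 ± 1.10 (log2, edgeR adjusted p = 0.0186). The list was higher by camera (adjusted p = 2.78e-06, and 0.422 with an estimated correlation). In library 0 of intMo, 13 of the 14 genes lay above the mean of the other two libraries, and in cMo library 0 all 14 lay below it. Without intMo 0 the log2 changes of H2-Ab1 and H2-Eb1 were 3.45 and 3.67. Without a filter on low counts the calls of H2-Ab1 and H2-Eb1 ended (edgeR adjusted p = 0.052 and 0.0554).

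Among 20 macrophage genes 12 rose, 2 fell and 6 were not called, with 13 higher and 2 lower when adjusted over the list alone. C1qa, a complement chain made by macrophages, rose by 5.11 ± 0.62 (log2, edgeR adjusted p = 0.000824), and Mertk, a receptor for the uptake of dying cells, rose by 4.50 ± 0.49 (edgeR adjusted p = 0.000494). The genes that fell, named after the values were seen, were Gpnmb, a glycoprotein of lipid-laden macrophages (log2 -2.29 ± 0.29), and Trem2, a lipid receptor (log2 -1.58 ± 0.19). Camera called the list higher (adjusted p = 0.0022, and 0.492 with an estimated correlation). Among 14 dendritic cell genes 9 rose, 1 fell and 4 were not called, with 10 higher and 1 lower when adjusted over the list alone. Fscn1, the actin bundler of migrating dendritic cells, rose by 5.82 ± 0.66 (log2, edgeR adjusted p = 0.000567). Mgl2, a lectin of dermal dendritic cells and named after the values were seen, fell by 2.66 ± 0.38 (log2, edgeR adjusted p = 0.00148). That list was higher by camera as well (adjusted p = 0.000433, and 0.397 with an estimated correlation).

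Of 10 Notch pathway genes, 6 rose and 4 were not called, also when adjusted over the list alone. Hes1, a repressor induced by Notch signalling, rose by 5.48 ± 0.51 (log2, edgeR adjusted p = 0.000218). Nrarp, a feedback inhibitor of Notch and named after the values were seen, rose by 5.0 ± 0.94 (log2, edgeR adjusted p = 0.006). The list was higher by camera (adjusted p = 0.0415, and 0.431 with an estimated correlation), a call lost without cMo 1, cMo 2, intMo 0 or intMo 2 (up to 0.194). Stromal cell genes were higher too, with 13 of 15 that rose, 1 that fell and 1 not called, and 14 higher and 1 lower when adjusted over the list alone. The camera test of the stromal list gave an adjusted p of 1.16e-08, and 0.399 with an estimated correlation. The stromal genes chosen after the values were seen were Col1a2, a collagen chain (log2 5.38 ± 0.79), Cxcl12, the chemokine that holds cells in marrow (log2 5.06 ± 0.34), and Dll1, the Notch ligand that the OP9-DLL1 line expresses (log2 4.76 ± 0.86). Mean Col1a2 was 1.37 ± 1.09 CPM in cMo and 57.6 ± 47.9 CPM in intMo, with 113 CPM in intMo library 0. Without that library the log2 changes of Col1a2 and Dll1 were 4.46 and 3.62. Igfbp4, a binding protein for growth factors, was the stromal gene that fell (log2 -1.66 ± 0.19, edgeR adjusted p = 0.000527).

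No gene of the 24 in the cell cycle list rose, 9 fell and 15 were not called, and 10 fell when adjusted over the list alone. Mcm2, a subunit of the replication helicase, fell by 1.83 ± 0.37 (log2, edgeR adjusted p = 0.00859), and its change was -1.11 with libraries 1 and 2 alone. The list was lower by camera (adjusted p = 5.83e-07, and 0.431 with an estimated correlation). The mean of these genes in intMo library 0 differed from that of the other two by -2.09 ± 0.65 (log2, SD over genes), and with libraries 1 and 2 alone all 24 were called lower. Granulocyte and progenitor genes included 5 that fell and 13 not called, and 5 were lower when adjusted over the list alone. They were Elane (log2 -2.83 ± 0.72), Mpo (log2 -3.18 ± 0.82), Prtn3 (log2 -2.74 ± 0.71) and Ctsg (log2 -3.62 ± 0.67), which encode granule enzymes, and Cd34, a progenitor antigen (log2 -1.88 ± 0.24). Elane, Prtn3 and Cd34 were named after the values were seen. Without cMo 0 the calls of Mpo (log2 -1.84), Elane (edgeR adjusted p = 0.069) and Prtn3 ended, as did that of Mpo without intMo 1 (up to 0.065) and that of Prtn3 without intMo 2 (up to 0.0741). S100a9, a calcium-binding protein of neutrophils, was not called (log2 -0.35 ± 1.02, edgeR adjusted p = 0.838), and its direction changed without cMo 0 (log2 1.04) or intMo 0 (log2 0.19). It was called higher with libraries 1 and 2 alone (log2 1.58, edgeR adjusted p = 0.000106). The list was lower by camera (adjusted p = 0.0275, and 0.67 with an estimated correlation), at 0.3 without cMo 0 and 0.202 without intMo 0. Its mean in library 0 differed from that of the other two by 2.12 ± 0.96 in cMo and -2.44 ± 1.16 in intMo (log2). The changes of Mpo, Elane and Prtn3 with libraries 1 and 2 alone were -1.38, -1.51 and -1.43, while 11 of the 18 genes were called higher and 6 lower, and the direction of the list by camera was up (adjusted p = 0.117).

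Inflammatory cytokine and NF-kB target genes rose in 9 of 15 cases and 6 were not called, also when adjusted over the list alone. Il1b, the cytokine interleukin 1 beta, rose by 5.05 ± 0.24 (log2, edgeR adjusted p = 6.64e-06). Cxcl1, a neutrophil chemokine, had 0 counts in cMo and 196 in intMo, which puts it at least 75.8-fold higher (floor of 3 counts over the subset). Camera called the list higher (adjusted p = 2.84e-06, and 0.422 with an estimated correlation). Immediate early and heat shock genes rose in 11 of 16 cases, with 5 not called, and 13 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.92e-05, and 0.422 with an estimated correlation). The mean of those genes in intMo library 0 lay 1.52 ± 1.30 above that of the other two (log2). Junb, a subunit of the AP-1 factor, rose by 1.44 ± 0.35 (edgeR adjusted p = 0.0173), a call lost without cMo 0 (0.0559). Fosb, a related subunit named after the values were seen, rose by 6.08 ± 1.82 (edgeR adjusted p = 0.0396). It had 298 CPM in intMo library 0 and 11.8 and 20.4 CPM in the others, its call was lost without cMo 0, cMo 1, cMo 2 or intMo 0 (up to 0.141), and its log2 change was 3.32 without intMo 0.

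Of 18 interferon-stimulated genes 3 rose and 15 were not called, and 1 rose when adjusted over the list alone. Among those that rose were Ifi44, an antiviral protein (log2 3.80 ± 1.17), and Ifih1, a sensor of viral RNA named after the values were seen (log2 1.40 ± 0.40). The call of Ifi44 (edgeR adjusted p = 0.0433) was lost without any 1 of 7 libraries, all but intMo 0 and pMo 0 (up to 0.0975). That of Ifih1 (edgeR adjusted p = 0.0336) was lost without any cMo library, intMo 1, intMo 2 or pMo 1 (up to 0.0907). The list was higher by camera (adjusted p = 0.00364, and 0.644 with an estimated correlation), at 0.0719 without cMo 0. Its mean in library 0 differed from that of the other two by -2.56 ± 0.86 in cMo and -1.59 ± 0.51 in intMo (log2), and with libraries 1 and 2 alone all 18 genes were called higher.

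The list of sterol synthesis genes and targets of the nuclear receptor LXR split, with 4 that rose, 13 that fell and 1 not called, and 4 and 14 when adjusted over the list alone. Those that rose were Nr1h3, which encodes LXR alpha (log2 4.33 ± 0.40), the cholesterol exporters Abca1 (log2 2.76 ± 0.65) and Abcg1 (log2 1.70 ± 0.36), and Mylip, a ubiquitin ligase (log2 1.37 ± 0.31). Abcg1 and Mylip were named after the values were seen. The changes of Abca1, Abcg1 and Mylip with libraries 1 and 2 alone were 1.69, 1.12 and 0.80. The list was lower by camera (adjusted p = 0.00365, and 0.422 with an estimated correlation). Lysosome genes rose in 6 of 18 cases and 12 were not called, also when adjusted over the list alone. Cd63, a membrane protein of lysosomes, rose by 1.89 ± 0.41 (log2, edgeR adjusted p = 0.0116), and Ctsl, a lysosomal protease, by 1.64 ± 0.19 (edgeR adjusted p = 0.000661). The lysosome list was higher by camera (adjusted p = 0.00721, and 0.447 with an estimated correlation), a call that ended with libraries 1 and 2 alone (0.0834).

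Among 17 chemokine receptor and integrin genes 5 rose, 4 fell and 8 were not called, with 5 higher and 6 lower when adjusted over the list alone. Among those that rose beside Itgax were the inflammatory chemokine receptor Ccr1 (log2 1.39 ± 0.17), Ccrl2, which presents the attractant chemerin (log2 1.42 ± 0.26), and S1pr1, the receptor for exit from tissue into blood (log2 2.06 ± 0.46). Among those that fell beside Ccr2 were Cxcr4, the receptor for marrow retention (log2 -0.90 ± 0.20), and Itgb7, an integrin of gut homing (log2 -0.95 ± 0.30). All but the core genes were named after the values were seen. The Itgb7 call (edgeR adjusted p = 0.0486) was lost without any 1 of 7 libraries, all but pMo 0 and pMo 2 (up to 0.132), and with RLE (0.051), upper quartile scaling (0.0654) or a filter at 1 CPM (0.0561). The list was not called by camera (adjusted p = 0.211, and 0.422 with an estimated correlation). Lymphoid genes rose in 6 of 10 cases and 4 were not called, also when adjusted over the list alone (camera adjusted p = 0.0048, and 0.397 with an estimated correlation). Of 8 erythroid, megakaryocyte, mast cell, basophil and eosinophil genes 2 fell and 6 were not called, also when adjusted over the list alone (camera adjusted p = 0.192, and 0.422 with an estimated correlation). Those were the basophil proteases Mcpt8 (log2 -2.93 ± 0.87) and Prss34 (log2 -2.34 ± 0.58), named after the values were seen. The call of Mcpt8 (edgeR adjusted p = 0.0379) was lost without cMo 0, cMo 2, any intMo library or pMo 2 (up to 0.126), and its change was -1.99 without cMo 0 and -1.53 with libraries 1 and 2 alone. That of Prss34 (edgeR adjusted p = 0.0193) was lost without cMo 2, intMo 0 or intMo 2 (up to 0.0669). Of 13 mitochondrially encoded genes mt-Nd1, a subunit of complex I named after the values were seen, fell (log2 -0.62 ± 0.17, edgeR adjusted p = 0.0286), 12 were not called and 0 were called when adjusted over the list alone (camera adjusted p = 0.0685, and 0.67 with an estimated correlation). That call was lost without cMo 0, cMo 2 or any intMo library (up to 0.0816), and the list was lower with libraries 1 and 2 alone (camera adjusted p = 0.00328), without cMo 0 (0.0101) and without pMo 0 (0.0231).

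Among called genes with a mean of at least 20 CPM over all 9 libraries, unnamed gene models left out, the largest rises beside Apol7c were those of Dnase1l3, a secreted DNase (log2 9.31 ± 0.33, edgeR adjusted p = 3.03e-06), Asb2, a ubiquitin ligase subunit (log2 8.34 ± 0.70), Pxdc1, a protein of unclear function (log2 8.03 ± 0.73), and Adamdec1, a secreted protease (log2 7.98 ± 0.46). Apol7c, an apolipoprotein L family member, had 2 counts in cMo and 7917 in intMo, a ratio of 4594 (95% counting interval 1271 to 37944). Beside Ctsg, Mpo and Fn1 the largest falls were those of Papss2, an enzyme that makes the sulfate donor (log2 -3.16 ± 0.32), and Slpi, an inhibitor of granule proteases (log2 -3.02 ± 0.51, edgeR adjusted p = 0.00374). The Mpo call was lost without cMo 0 (log2 -1.84) and without intMo 1.

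In the edgeR quasi-likelihood test 3433 of 14059 genes were called at an adjusted p under 0.05, of which 1966 were higher and 1467 lower in intMo. Of these, 1515 higher and 679 lower genes changed at least 2-fold. Libraries 1 and 2 alone gave 3936 called genes, 2242 higher and 1694 lower, and 2874 of them were also called with all libraries, all 2874 in the same direction. When the fit held only the 6 libraries compared, 2213 genes were called, and when the test was made against a log2 change of 1, 874. The fit to 6 libraries ended the calls of Mpo (edgeR adjusted p = 0.059), Elane (0.0547), Prtn3 (0.0543), Ifi44 (0.0601), Ifih1 (0.0576), Mcpt8 (0.0546) and Cebpb (0.0826). Without a filter on low counts the edgeR calls of Ly6c2 (adjusted p = 0.118), Ifi44 (0.111), Fosb (0.125), Mpo (0.0651), Elane (0.0635), Prtn3 (0.0649), Ifih1 (0.0592), Mcpt8 (0.0553), Cebpb (0.0606) and Itgb7 (0.0545) ended.

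Patrolling monocytes were then compared with intermediate monocytes, which asks what separates these neighbouring subsets. S1pr5, the sphingosine phosphate receptor that patrolling monocytes need to leave the marrow, rose from 0.184 ± 0.0671 to 41.2 ± 3.44 CPM (mean ± SD, n = 3), a log2 fold change of 7.72 ± 0.44 (SE, edgeR adjusted p = 7.19e-05). Spn rose from 99.2 ± 37.5 to 551 ± 60.4 CPM (log2 2.47 ± 0.29, edgeR adjusted p = 0.00245), and Nr4a1 rose from 1923 ± 386 to 4490 ± 534 CPM (log2 1.22 ± 0.18, edgeR adjusted p = 0.00598). Itgax rose from 963 ± 178 to 1727 ± 262 CPM (log2 0.84 ± 0.20, edgeR adjusted p = 0.0478), and Treml4 rose from 230 ± 23.6 to 434 ± 41.5 CPM (log2 0.92 ± 0.17, edgeR adjusted p = 0.0179). In the 4 core genes among these the libraries of the subsets did not overlap, an outcome that chance gives for 10% of genes. The Itgax call was lost without cMo 1, intMo 1, intMo 2 or any pMo library (edgeR adjusted p up to 0.157), and that of Treml4 without intMo 1, intMo 2, pMo 1 or pMo 2 (up to 0.0889). The Itgax call also ended with the other normalizations (0.0546 and 0.0657) and with a filter at 1 CPM (0.0519).

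The remaining core genes were not called by edgeR with all libraries and no block. Cx3cr1 had 378 ± 40.9 CPM in pMo and 111 ± 15.7 CPM in intMo (log2 1.77 ± 0.47, adjusted p = 0.0685 by edgeR and 0.0018 by DESeq2). Ccr2 had 371 ± 56 CPM in pMo and 761 ± 123 CPM in intMo (log2 -1.04 ± 0.28, adjusted p = 0.0696 by edgeR and 0.00661 by DESeq2), and was called by edgeR with the replicate number as a block (0.0268). With only the 6 libraries compared, edgeR called Cx3cr1 (0.00209) and Ccr2 (0.0147). Ly6c2 had 53.2 ± 38.5 CPM in pMo and 163 ± 122 CPM in intMo (log2 -1.61 ± 0.86, edgeR adjusted p = 0.371), and H2-Ab1 had 735 ± 768 and 1416 ± 1072 CPM (log2 -0.95 ± 0.91, edgeR adjusted p = 0.672). Adgre1 (log2 -0.54 ± 0.34, edgeR adjusted p = 0.456), Csf1r (log2 -0.08 ± 0.29, edgeR adjusted p = 0.931) and Itgam (log2 0.05 ± 0.15, edgeR adjusted p = 0.923) differed by less than 1 on the log2 scale. With libraries 1 and 2 alone, Cx3cr1 (edgeR adjusted p = 0.000135), Ccr2 (0.00295), Ly6c2 (0.000339), H2-Ab1 (0.000194) and Adgre1 (0.0343) were called in these directions. The direction for Itgam changed with upper quartile scaling (log2 -0.01) and without intMo 1 (log2 -0.03) or pMo 1 (log2 -0.01), and that for Csf1r without intMo 0 (log2 0.25).

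Of 24 patrolling monocyte genes 19 rose, none fell and 5 were not called, and 20 rose when adjusted over the list alone. Ace rose by 4.71 ± 0.49 (log2, edgeR adjusted p = 0.00136). Klf2 rose by 1.94 ± 0.23 (edgeR adjusted p = 0.00257) and Dusp16, a phosphatase that acts on stress kinases, by 2.55 ± 0.14 (edgeR adjusted p = 5.27e-05), both named after the values were seen. Camera called the list higher (adjusted p = 5.66e-21, and 0.0632 with an estimated correlation). None of 14 conventional monocyte genes was called by edgeR, over all genes or adjusted over the list alone, while 4 were lower at an unadjusted p under 0.05 and 3 by DESeq2. The list was not called by camera (adjusted p = 0.627, and 0.916 with an estimated correlation). With libraries 1 and 2 alone 3 of these genes were called higher and 7 lower, and the list was lower (0.0318).

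Of 14 dendritic cell genes 5 fell and 9 were not called, with 1 higher and 6 lower when adjusted over the list alone. Siglech, a lectin of plasmacytoid dendritic cells, fell from 35 ± 1.57 to 0.649 ± 0.295 CPM (log2 -5.75 ± 0.31, edgeR adjusted p = 5.27e-05). Flt3, the receptor for the dendritic cell growth factor, fell (log2 -3.22 ± 0.65, edgeR adjusted p = 0.0249), as did Mgl2 (log2 -2.38 ± 0.39, edgeR adjusted p = 0.0104) and Clec9a, a receptor for dead cells that was named after the values were seen (log2 -4.26 ± 0.41, edgeR adjusted p = 0.000958). Cd209a, the lectin DC-SIGN, had 59 counts in intMo and 2 in pMo, a ratio of 30.9 (95% counting interval 8.18 to 261). The Flt3 call was lost without intMo 1, intMo 2, pMo 1 or pMo 2 (edgeR adjusted p up to 0.113) and that of Mgl2 without pMo 1 or pMo 2 (up to 0.062). The list was lower by camera (adjusted p = 0.000567, and 0.397 with an estimated correlation). Of 20 macrophage genes 1 rose and 19 were not called, with 2 higher and 7 lower when adjusted over the list alone. The gene that rose was Spp1, the matrix protein osteopontin (log2 2.80 ± 0.43, edgeR adjusted p = 0.00846), against the direction of the list, which was lower by camera (adjusted p = 0.00365, and 0.512 with an estimated correlation) but not without intMo 0 (0.0833). C1qa (log2 -2.08 ± 0.54, edgeR adjusted p = 0.0664) and Mrc1, the mannose receptor (log2 -2.62 ± 0.68, edgeR adjusted p = 0.0655), were named after the values were seen and were not called by edgeR, but were called by DESeq2 (0.000963 and 0.000324) and with libraries 1 and 2 alone (7.19e-05 and 2.05e-05). Among macrophage genes 2 were called higher and 11 lower with libraries 1 and 2 alone. No MHC class II gene of 14 was called by edgeR, over all genes or adjusted over the list alone, or by DESeq2, and 2 were lower at an unadjusted p under 0.05. The list was not called by camera (adjusted p = 0.209, and 0.78 with an estimated correlation). With libraries 1 and 2 alone 1 gene was called higher and 8 lower, and the list was lower (0.0045).

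Of 15 inflammatory cytokine and NF-kB target genes 4 rose and 11 were not called, also when adjusted over the list alone. They were the cytokine Tnf (log2 1.68 ± 0.25, edgeR adjusted p = 0.00623), the chemokines Ccl4 (log2 1.89 ± 0.32, edgeR adjusted p = 0.0123) and Ccl3 (log2 0.91 ± 0.21, edgeR adjusted p = 0.0436), and Nfkbia, an inhibitor of NF-kB (log2 1.16 ± 0.24, edgeR adjusted p = 0.0263), of which Ccl3 and Nfkbia were named after the values were seen. The Ccl4 call was lost without intMo 1 or pMo 1 (up to 0.0601). That of Ccl3 was lost without cMo 1, intMo 1, intMo 2 or any pMo library (up to 0.15) or with a filter at 1 CPM (0.0501), and that of Nfkbia without the same libraries other than cMo 1 (up to 0.108). The list, with a median log2 change of -0.01 and a mean of 0.09, was not called by camera (higher, adjusted p = 0.174, and 0.754 with an estimated correlation). Of 16 immediate early and heat shock genes 2 rose and 14 were not called, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.271, and 0.798 with an estimated correlation). Those were Egr3, a factor induced by antigen receptors (log2 2.10 ± 0.26, edgeR adjusted p = 0.00307), and Nr4a3, a relative of Nr4a1 (log2 2.35 ± 0.52, edgeR adjusted p = 0.0335), both named after the values were seen. The Nr4a3 call was lost without intMo 1, intMo 2 or any pMo library (up to 0.13). The mean of these genes in pMo library 0 lay 1.23 ± 1.43 above that of the other two (log2).

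Among 17 chemokine receptor and integrin genes 5 rose, 2 fell and 10 were not called, with 7 higher and 4 lower when adjusted over the list alone. Beside S1pr5 and Itgax, Itgal (log2 1.11 ± 0.18, edgeR adjusted p = 0.0102) and Itgb2 (log2 0.75 ± 0.11, edgeR adjusted p = 0.00592), the subunits of the integrin LFA-1 with which patrolling monocytes crawl on vessels, rose, as did Ccrl2 (log2 1.11 ± 0.25, edgeR adjusted p = 0.0387). Ccr1 was among those that fell (log2 -1.22 ± 0.16, edgeR adjusted p = 0.00407). Itgal, Itgb2 and Ccrl2 were named after the values were seen. The Itgax and Ccrl2 calls were lost without cMo 1, intMo 1, intMo 2 or any pMo library (up to 0.157 and 0.155), and that of Itgal without pMo 1 (0.0579). The list was higher by camera (adjusted p = 0.0304, and 0.397 with an estimated correlation) but not without intMo 0 (0.0548), without pMo 1 (0.0505) or with libraries 1 and 2 alone (0.117).

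Of 10 Notch pathway genes 1 fell and 9 were not called, with 1 higher and 1 lower when adjusted over the list alone. It was the receptor Notch1 (log2 -1.32 ± 0.29, edgeR adjusted p = 0.0331), a call lost without cMo 1, intMo 0, intMo 2 or any pMo library (up to 0.144). Hes1 (log2 0.02 ± 0.40, edgeR adjusted p = 0.989) and Nrarp (log2 1.29 ± 0.74, edgeR adjusted p = 0.411) were not called, though Nrarp was with libraries 1 and 2 alone (0.00479). The direction for Hes1 changed with upper quartile scaling (log2 -0.04) and without intMo 1, intMo 2 or pMo 0 (down to log2 -0.31). The list was not called by camera (adjusted p = 0.651, and 0.851 with an estimated correlation). No stromal gene of 15 was called by edgeR, over all genes or adjusted over the list alone, or by DESeq2, and 1 was lower at an unadjusted p under 0.05. The list was not called by camera (adjusted p = 0.66, and 0.927 with an estimated correlation). Col1a2, named after the values were seen, had 49.7 ± 23.2 CPM in pMo and 57.6 ± 47.9 CPM in intMo (log2 -0.21 ± 0.63, edgeR adjusted p = 0.915), and its direction changed without intMo 0 (log2 0.72) or pMo 2 (log2 0.04). None of 24 cell cycle genes was called by edgeR, over all genes or adjusted over the list alone, while 14 were lower at an unadjusted p under 0.05 and 5 by DESeq2. The list was lower by camera (adjusted p = 2.38e-05, and 0.492 with an estimated correlation). Its mean in library 0 differed from that of the other two by -0.82 ± 0.67 in pMo and -2.09 ± 0.65 in intMo (log2), and with libraries 1 and 2 alone all 24 genes were called lower.

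Of 18 sterol synthesis and LXR target genes 1 rose and 17 were not called, with 2 higher when adjusted over the list alone. The gene was Msmo1, an enzyme of cholesterol synthesis (log2 1.04 ± 0.21, edgeR adjusted p = 0.0232), a call lost without intMo 2, pMo 1 or pMo 2 (up to 0.0996). Camera called the list higher (adjusted p = 0.000415, and 0.397 with an estimated correlation). Of 18 lysosome genes 2 rose, 1 fell and 15 were not called, also when adjusted over the list alone. Tfeb, the factor that drives lysosome genes and was named after the values were seen, rose by 0.56 ± 0.13 (log2, edgeR adjusted p = 0.0384), and Ctsl fell (log2 -1.30 ± 0.19, edgeR adjusted p = 0.00676). The call of Tfeb was lost without cMo 1 or any intMo or pMo library (up to 0.137). The list, with a median of 0.01 and a mean of -0.01, was not called by camera (higher, adjusted p = 0.807, and 0.929 with an estimated correlation).

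Of 10 lymphoid genes 1 rose, 1 fell and 8 were not called, with 2 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.112, and 0.431 with an estimated correlation). Klrb1c, the natural killer receptor NK1.1, rose (log2 2.07 ± 0.44, edgeR adjusted p = 0.028) and Il7r, the receptor for interleukin 7, fell (log2 -1.67 ± 0.37, edgeR adjusted p = 0.0345), both named after the values were seen. The Klrb1c call was lost without intMo 1, intMo 2 or any pMo library (up to 0.121) and that of Il7r without any 1 of 7 libraries, all but cMo 0 and pMo 0 (up to 0.147). The lymphoid list was lower with libraries 1 and 2 alone (camera adjusted p = 0.0113). None of the 18 granulocyte and progenitor genes, 18 interferon-stimulated genes or 13 mitochondrially encoded genes was called by edgeR, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 3, 0 and 0, and by DESeq2 2, 0 and 0. Their lists were not called by camera, with adjusted p values of 0.109, 0.744 and 0.414, and of 0.754, 0.929 and 0.851 with an estimated correlation. The granulocyte list was lower with libraries 1 and 2 alone (6.4e-09), with 12 genes called lower. In pMo library 0 the mean of these genes differed from that of the other two by -1.30 ± 1.23 (log2), and that of the interferon-stimulated genes by -1.86 ± 0.58. None of 8 erythroid, megakaryocyte, mast cell, basophil and eosinophil genes was called by edgeR over all genes, 1 was lower when adjusted over the list alone, 2 at an unadjusted p under 0.05 and 1 by DESeq2. That list was lower by camera (adjusted p = 0.0406, and 0.397 with an estimated correlation), a call lost without any 1 of 7 libraries, all but intMo 0 and pMo 0 (up to 0.193), and with a filter at 1 CPM (0.182).

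Among called genes with a mean of at least 20 CPM over all 9 libraries, the largest rises beside Ace were those of Eno3, a glycolytic enolase (log2 4.11 ± 0.19, edgeR adjusted p = 4.63e-05), Ly6i, a relative of Ly6c2 (log2 3.78 ± 0.59), L1cam, an adhesion molecule (log2 3.74 ± 0.25), and Tiam2, an activator of the GTPase Rac (log2 3.50 ± 0.40). Bcl6, a transcriptional repressor, was named after the values were seen and rose by 2.06 ± 0.13 (log2, edgeR adjusted p = 0.000104). The largest falls among such called genes were those of Flt3, Mgl2, Dmpk, a muscle kinase (log2 -3.07 ± 0.54, edgeR adjusted p = 0.0137), Tlr12, a receptor for profilin (log2 -2.52 ± 0.49, edgeR adjusted p = 0.0204), and Fcrls, a scavenger receptor of microglia (log2 -2.42 ± 0.53, edgeR adjusted p = 0.0334). The calls of Dmpk, Tlr12 and Mgl2 were lost without pMo 1 or pMo 2 (up to 0.0774, 0.108 and 0.062), that of Flt3 also without intMo 1 or intMo 2 (up to 0.113), and that of Fcrls without cMo 1 or any intMo or pMo library (up to 0.149).

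In the edgeR test 701 genes were called, 463 higher and 238 lower in pMo, of which 271 and 178 changed at least 2-fold. The count was 221 without pMo 1, 257 without pMo 2, 303 without intMo 2, 321 without intMo 1, 446 without pMo 0 and 1107 without cMo 0. Libraries 1 and 2 alone, with 2 libraries per subset and a smaller spread, gave 2424 called genes, 1053 higher and 1371 lower. Of these, 691 were also called with all libraries, in the same direction, though both fits hold libraries 1 and 2. DESeq2 called 1417 genes, of which 54.3% were higher, against 66% by edgeR. Against a log2 change of 1, 60 genes were called. With only the 6 libraries compared the calls of Flt3 (edgeR adjusted p = 0.0582) and Il7r (0.0538) ended, and Mrc1 was called (0.0227). Without a filter on low counts the edgeR calls of Flt3 (adjusted p = 0.0626), Fcrls (0.0814) and Tfeb (0.0576) ended, and with upper quartile scaling those of Ccl3 (0.0635), Ccrl2 (0.0526) and Tfeb (0.0598). With the replicate number as a block those of Fcrls (0.0728), Ccl3 (0.0582), Ccrl2 (0.0578) and Tfeb (0.0521) ended. Without intMo 0 camera called the conventional monocyte (adjusted p = 0.019) and granulocyte (0.000162) lists lower and the inflammatory cytokine (0.0128) and immediate early (0.0112) lists higher. Without pMo 0 it called the MHC class II (0.0147) and lymphoid (0.0107) lists lower.

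Patrolling monocytes were last compared with conventional monocytes, the widest of the 3 comparisons. Ly6c2 fell by 4.48 ± 0.97 on the log2 scale (SE, n = 3 per subset, edgeR adjusted p = 0.00772), and Ccr2 fell by 2.29 ± 0.29 (edgeR adjusted p = 0.00056). Itgax rose by 6.19 ± 0.25 (edgeR adjusted p = 1.61e-06), Treml4 by 4.57 ± 0.20 (edgeR adjusted p = 2.17e-06) and Nr4a1 by 4.28 ± 0.20 (edgeR adjusted p = 3.05e-06). Cx3cr1 rose from 77.3 ± 47.7 to 378 ± 40.9 CPM (log2 2.29 ± 0.48, edgeR adjusted p = 0.0064), and Spn from 277 ± 52.9 to 551 ± 60.4 CPM (log2 0.99 ± 0.28, edgeR adjusted p = 0.0224). Csf1r rose to 3628 ± 356 CPM (log2 1.43 ± 0.29, edgeR adjusted p = 0.00587), Adgre1 to 663 ± 101 CPM (log2 1.15 ± 0.34, edgeR adjusted p = 0.0294) and H2-Ab1 to 735 ± 768 CPM (log2 3.32 ± 0.98, edgeR adjusted p = 0.0293). Itgam was not called at 902 ± 85.5 CPM (log2 0.17 ± 0.15, edgeR adjusted p = 0.399). All of these but Itgam had all 3 libraries of one subset above all 3 of the other, where chance gives 10%. The Spn call was lost without cMo 1, cMo 2, pMo 0 or pMo 1 (up to 0.0759), that of Adgre1 without any pMo library (up to 0.0864), and that of H2-Ab1 without any cMo library or pMo 0 (up to 0.112, log2 2.0 without pMo 0). The changes of H2-Ab1 and Adgre1 with libraries 1 and 2 alone were 1.5 and 0.69.

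All 24 patrolling monocyte genes rose, also when adjusted over the list alone. Ace, at 0.865 ± 0.497 CPM in cMo and 1360 ± 679 CPM in pMo, rose by 10.61 ± 0.65 (log2, edgeR adjusted p = 1.37e-05). Bcl2a1b, a survival factor with near-identical copies, rose by 7.38 ± 0.34 (edgeR adjusted p = 3.05e-06), and S1pr5 by 6.31 ± 0.40 (edgeR adjusted p = 1.37e-05). Eno3 (log2 5.97 ± 0.21), Dusp16 (log2 4.80 ± 0.15) and Pparg, a nuclear receptor of lipid metabolism (log2 4.15 ± 0.48), were named after the values were seen. The list was higher by camera (adjusted p = 2.77e-18, and 0.0632 with an estimated correlation). Of 14 conventional monocyte genes 10 fell, none rose and 4 were not called, with 11 lower when adjusted over the list alone (camera adjusted p = 0.000123, and 0.422 with an estimated correlation).

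**Figure D3:**
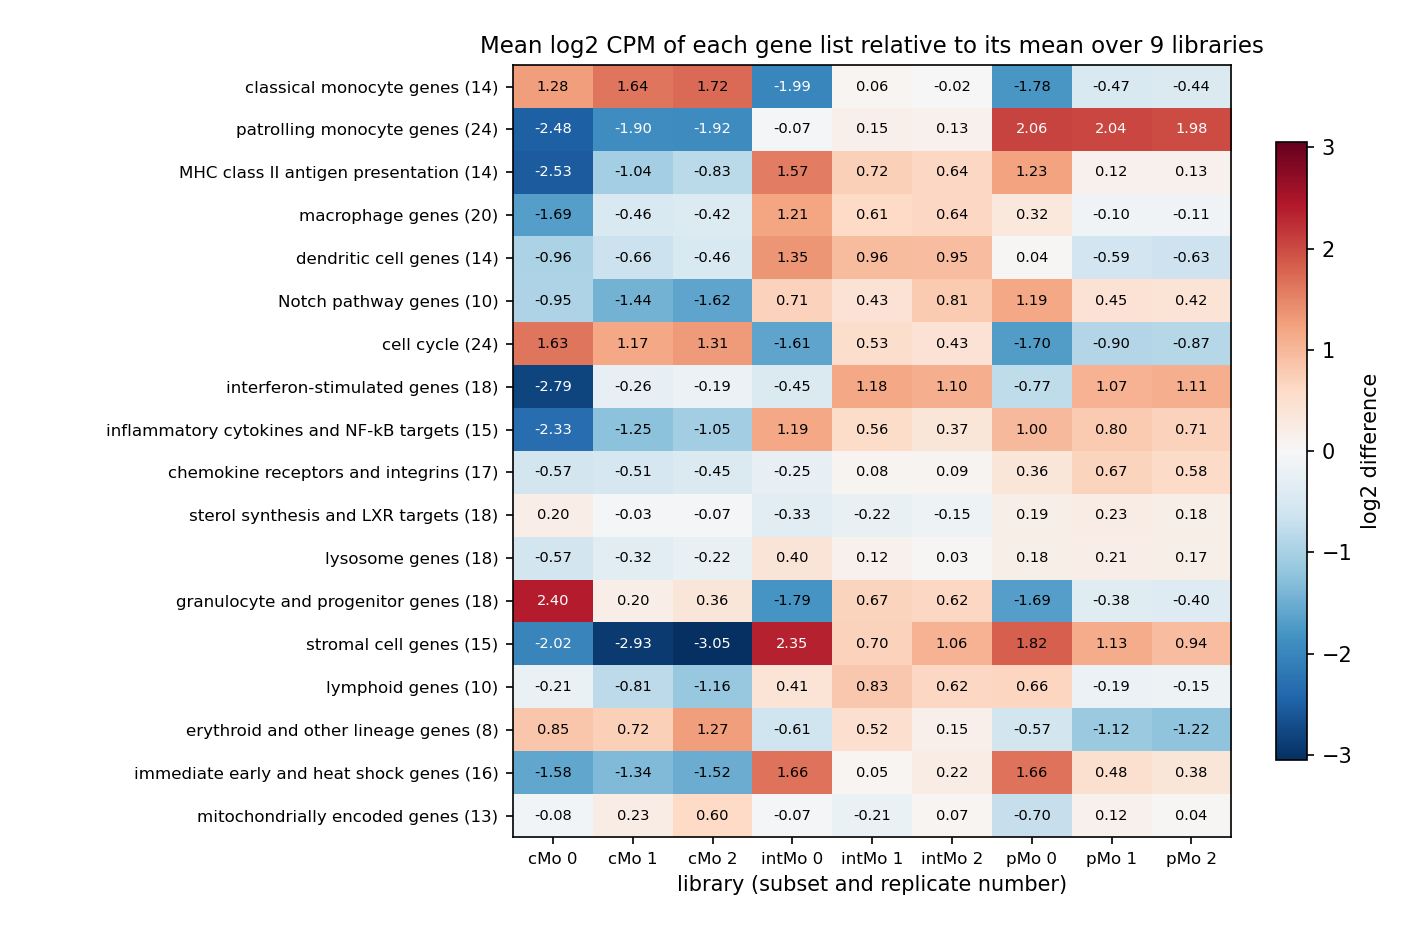
Mean log2 level of each gene list in each library, relative to the mean of that list over all 9 libraries. Patrolling monocyte genes lay between -2.48 and -1.9 in cMo, between -0.07 and 0.15 in intMo and between 1.98 and 2.06 in pMo, while granulocyte and progenitor genes were at 2.4 in cMo library 0 and at -1.79 in intMo library 0.

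Of 14 MHC class II genes 12 rose and 2 were not called, also when adjusted over the list alone (camera adjusted p = 0.000259, and 0.431 with an estimated correlation). H2-Eb1 rose by 3.68 ± 1.06 (log2, edgeR adjusted p = 0.026), a call lost without any cMo library or pMo 0 (up to 0.0954, log2 2.23 without pMo 0), and its change was 1.72 with libraries 1 and 2 alone. In pMo library 0, 11 of the 14 genes lay above the mean of the other two. Of 20 macrophage genes 12 rose, 4 fell and 4 were not called, also when adjusted over the list alone (camera adjusted p = 0.0594, and 0.67 with an estimated correlation). The macrophage list was called higher by camera with a filter at 1 CPM (0.021) and without cMo 1 (0.0323) or cMo 2 (0.0242). Mertk rose by 3.06 ± 0.46 (log2, edgeR adjusted p = 0.00147). Those that fell were Gpnmb (log2 -1.28 ± 0.28), Trem2 (log2 -1.45 ± 0.19), Cd163, a scavenger receptor for haemoglobin (log2 -3.29 ± 0.77), and Folr2, a folate receptor of resident macrophages (log2 -1.94 ± 0.49), with edgeR adjusted p between 0.00063 and 0.0145. Gpnmb, Trem2 and Folr2 were named after the values were seen.

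Dendritic cell genes split, with 5 that rose, 5 that fell and 4 not called, and 5 and 6 when adjusted over the list alone (camera adjusted p = 0.819, and 0.929 with an estimated correlation). Those that rose were the transcription factors Zbtb46 (log2 3.71 ± 0.39) and Batf3 (log2 4.27 ± 0.41) of conventional dendritic cells, the lymph node homing receptor Ccr7 (log2 4.31 ± 0.61), Fscn1 (log2 4.79 ± 0.64) and the peptidase Dpp4 (log2 3.17 ± 0.32). Those that fell were Flt3 (log2 -3.77 ± 0.67), the lectins Clec10a (log2 -2.69 ± 0.64), Siglech (log2 -2.67 ± 0.29) and Mgl2 (log2 -5.04 ± 0.43), and Cd209a, with 21 counts in cMo and 2 in pMo (ratio 9.47, 95% counting interval 2.32 to 83.3). All but Fscn1 and Mgl2 were named after the values were seen. Of 10 Notch pathway genes 7 rose, 1 fell and 2 were not called, also when adjusted over the list alone (camera adjusted p = 0.0275, and 0.422 with an estimated correlation). Nrarp rose by 6.29 ± 0.97 (log2, edgeR adjusted p = 0.00163) and Hes1 by 5.50 ± 0.51 (edgeR adjusted p = 0.000125), while Notch1, named after the values were seen, fell (log2 -1.81 ± 0.29, edgeR adjusted p = 0.00186). Stromal cell genes again rose in 13 of 15 cases, with 1 lower and 1 not called, and 14 higher and 1 lower when adjusted over the list alone (camera adjusted p = 3.04e-07, and 0.422 with an estimated correlation). Col1a2 (log2 5.17 ± 0.78) and Cxcl12 (log2 4.81 ± 0.34) rose and were named after the values were seen, and Igfbp4 fell (log2 -2.23 ± 0.19, edgeR adjusted p = 8.25e-05).

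All 24 cell cycle genes fell, also when adjusted over the list alone (camera adjusted p = 7.54e-10, and 0.422 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 3.33 ± 0.67 (log2, edgeR adjusted p = 0.00562) and Ccne1, the cyclin of entry into DNA synthesis, by 3.17 ± 0.50 (edgeR adjusted p = 0.00182). Of 18 granulocyte and progenitor genes 6 fell and 12 were not called, also when adjusted over the list alone. Among the 6, Ctsg (log2 -5.72 ± 0.75), Prtn3 (log2 -4.85 ± 0.79), Mpo (log2 -4.83 ± 0.89) and Elane (log2 -4.55 ± 0.79) had the largest falls beside Mgl2 among called genes with a mean of at least 20 CPM over all 9 libraries. Without cMo 0 the log2 changes of Mpo, Elane and Prtn3 were -3.5, -3.72 and -4.01, smaller falls than that of Ly6c2 in the same fit. S100a9 was not called (log2 -1.06 ± 1.03, edgeR adjusted p = 0.463), and its direction changed without cMo 0 (log2 0.33). It was called higher with libraries 1 and 2 alone (log2 0.81, edgeR adjusted p = 0.00224). The granulocyte list was lower by camera (adjusted p = 0.00532, and 0.607 with an estimated correlation) but not without cMo 0 (0.0701) or with libraries 1 and 2 alone (0.682), when 8 genes were called higher and 7 lower. Cell cycle genes lay 0.39 ± 0.43 higher in cMo library 0 than in the other two (log2).

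Of 15 inflammatory cytokine and NF-kB target genes 11 rose and 4 were not called, also when adjusted over the list alone (camera adjusted p = 2.84e-06, and 0.422 with an estimated correlation). Il1b rose by 5.30 ± 0.24 (log2, edgeR adjusted p = 2.67e-06). Cxcl1 had 162 counts in pMo and 0 in cMo, at least 59.9-fold higher. Of 16 immediate early and heat shock genes 11 rose and 5 were not called, also when adjusted over the list alone (camera adjusted p = 0.000144, and 0.422 with an estimated correlation). Junb rose by 1.46 ± 0.35 (edgeR adjusted p = 0.0118). Fosb, named after the values were seen, rose by 5.72 ± 1.80 (edgeR adjusted p = 0.0371), a call lost without any cMo library or pMo 0 (up to 0.183, log2 2.60 without pMo 0), and its change was 3.15 with libraries 1 and 2 alone. Of 18 interferon-stimulated genes 3 rose and 15 were not called, with 2 higher when adjusted over the list alone. Among those that rose were Isg15, a ubiquitin-like antiviral protein (log2 2.22 ± 0.75, edgeR adjusted p = 0.0479), and Ifih1 (log2 1.61 ± 0.40, edgeR adjusted p = 0.0148). The call of Isg15 was lost without any 1 of 7 libraries, all but intMo 0 and pMo 0 (up to 0.127), and that of Ifih1 without pMo 2 (0.052). Camera called the list higher (adjusted p = 0.0136, and 0.67 with an estimated correlation) but not without cMo 0 (0.17) or pMo 2 (0.0548), and with libraries 1 and 2 alone all 18 genes were called higher.

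Of 18 sterol synthesis and LXR target genes 3 rose, 3 fell and 12 were not called, with 3 higher and 5 lower when adjusted over the list alone. Nr1h3 (log2 5.22 ± 0.41, edgeR adjusted p = 6.12e-05), Abcg1 (log2 1.46 ± 0.36) and Mylip (log2 1.59 ± 0.31) rose. Srebf1, a regulator of lipid synthesis, was among those that fell (log2 -0.77 ± 0.25, edgeR adjusted p = 0.0432). All but Nr1h3 were named after the values were seen. The call of Srebf1 was lost without cMo 0, cMo 1, intMo 2, pMo 1 or pMo 2 (up to 0.146). The change of Abcg1 with libraries 1 and 2 alone was 0.88. The list, with a median of -0.42 and a mean of 0.10, was not called by camera (lower, adjusted p = 0.265, and 0.67 with an estimated correlation). Of 18 lysosome genes 8 rose and 10 were not called, also when adjusted over the list alone (camera adjusted p = 0.0175, and 0.492 with an estimated correlation, 0.0719 without cMo 0). Cd63 rose by 2.15 ± 0.42 (log2, edgeR adjusted p = 0.00476) and Ctsb, a lysosomal protease, by 1.60 ± 0.28 (edgeR adjusted p = 0.0027).

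Of 17 chemokine receptor and integrin genes 9 rose, 2 fell and 6 were not called, also when adjusted over the list alone (camera adjusted p = 0.0182, and 0.397 with an estimated correlation). Of 10 lymphoid genes 3 rose and 7 were not called, also when adjusted over the list alone (camera adjusted p = 0.057, and 0.422 with an estimated correlation). The genes that rose were Klrb1c (log2 4.81 ± 0.52), Il7r (log2 1.25 ± 0.38, edgeR adjusted p = 0.0323) and Ebf1, a factor of B cell and stromal lineages (log2 1.98 ± 0.38), all named after the values were seen. The Il7r call was lost without cMo 1, cMo 2, intMo 2 or pMo 0 (up to 0.101), with a change of 0.70 without pMo 0. The lymphoid list was called higher by camera with a filter at 1 CPM (0.0401) and without cMo 0 (0.0421), pMo 1 (0.026) or pMo 2 (0.04). Of 8 erythroid, megakaryocyte, mast cell, basophil and eosinophil genes 2 fell and 6 were not called, also when adjusted over the list alone. Mcpt8 fell by 4.99 ± 1.01 (log2, edgeR adjusted p = 0.00561, log2 -4.05 without cMo 0) and Prss34 had 99 counts in cMo and 1 in pMo (ratio 89.3, 95% counting interval 15.7 to 3562), both named after the values were seen. That list was lower by camera (adjusted p = 0.0313, and 0.397 with an estimated correlation), a call lost without any 1 of 7 libraries, all but intMo 0 and pMo 0 (up to 0.0781), and with a filter at 1 CPM (0.295). Of 13 mitochondrially encoded genes 1 fell and 12 were not called, also when adjusted over the list alone. It was mt-Nd1, named after the values were seen (log2 -0.68 ± 0.17, edgeR adjusted p = 0.0145). The mitochondrial list was lower by camera (adjusted p = 0.0289, and 0.644 with an estimated correlation) but not without cMo 2 (0.153) or pMo 0 (0.187).

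Among called genes with a mean of at least 20 CPM over all 9 libraries the largest rises beside Ace and Apol7c were those of Dnase1l3 (log2 8.86 ± 0.32, edgeR adjusted p = 8.36e-07), Adamdec1 (log2 8.22 ± 0.46) and Bcl2a1a, a copy of Bcl2a1b (log2 8.10 ± 0.32). Apol7c had 1792 counts in pMo and 2 in cMo, a ratio of 993 (95% counting interval 275 to 8208). In the edgeR test 4650 genes were called, 2420 higher and 2230 lower in pMo, of which 1615 and 1210 changed at least 2-fold. Libraries 1 and 2 alone gave 5349 called genes, 2797 higher and 2552 lower, and 4214 of them were also called with all libraries, in the same direction. Against a log2 change of 1, 1303 genes were called. The calls of Isg15 (edgeR adjusted p = 0.0511), Srebf1 (0.0577) and Il7r (0.0718) ended in the fit to the 6 libraries compared. Without a filter on low counts the edgeR calls of H2-Ab1 (adjusted p = 0.0821), H2-Eb1 (0.0743), Isg15 (0.122) and Fosb (0.12) ended. Across all 3 subsets at once 4644 genes were called by the edgeR F test, and 5399 with libraries 1 and 2 alone.

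The position of intMo between the other subsets was taken over the 2825 genes called between pMo and cMo with at least a 2-fold change, as the intMo to cMo change divided by the pMo to cMo change of the fitted log2 values. The median was 0.73, where 0 is the level of cMo and 1 that of pMo. Of these genes 52.7% lay above 0.5 and up to 1, 18.7% from 0 to 0.5, 25.9% above 1 and 2.8% below 0. The median was 0.88 for the 1615 genes higher in pMo and 0.62 for the 1210 lower genes. The median for the single libraries was 0.99 in intMo 0, 0.63 in intMo 1 and 0.67 in intMo 2, and it was 0.66 with libraries 1 and 2 alone. In simulated counts the median was 0.04 when intMo was drawn as cMo and 0.97 when it was drawn as pMo. These genes are not independent replicates, so no p-value was given.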

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

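The fit to libraries 1 and 2 alone was chosen after the result was seen, and the other alternatives before. It rests on 2 libraries per subset, those most alike, so its spread is smaller. Of 180 gene results, 163 were called, 87 of them under every alternative run and 121 on leaving out any 1 library. For lists these numbers were 54, 36, 0 and 25. Testing genes against a log2 change of 1 ended 76 calls, leaving the 87. The largest loss of list calls came with an estimated correlation, which gave 0 called lists in each of the 3 contrasts against 15, 7 and 14. This test allows for genes of a list that move together, and its lowest adjusted p was 0.0632. The count of genes between pMo and intMo ranged from 221 (without pMo 1) to 1107 (without cMo 0) with 1 library left out, and was 1417 with DESeq2 and 2424 with libraries 1 and 2 alone. The count between intMo and cMo was 2213 with only the 6 libraries compared. Against a log2 change of 1, which asks for more than a change from 0, the counts were 874, 60 and 1303. The other counts stayed within 1.5 times, with ranges on leaving out 1 library of 2337 to 3284 between intMo and cMo, 3138 to 4962 between pMo and cMo, and 3184 to 4452 over any subset. Their own number best matched 4 of 9 libraries, each library 0 and pMo 1, too few to pair 1 and 2. The replicate block gave 3650, 836 and 4961 genes. Between pMo and intMo it changed only the calls of Ccr2, Fcrls, Ccl3, Ccrl2, Tfeb and Trf among the genes and lists reported. Interferon-stimulated genes were lower in each library 0. Deviations of cMo and other same-number libraries correlated at -0.14 to 0.23, so against cMo none was paired. There the block moved the adjusted p of Mpo (0.0771), Elane (0.0561), Prtn3 (0.0573), Mcpt8 (0.0935), Cebpb (0.0668) and the granulocyte list (0.0592) past 0.05 between intMo and cMo, and that of the mitochondrial list (0.041) under it. Between pMo and cMo it moved those of H2-Ab1 (0.0999), H2-Eb1 (0.0917) and Adgre1 (0.0607) past 0.05 and that of the lymphoid list (0.0346) under it. The position of intMo stayed between 0.66 and 0.78.

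Directions that changed belonged to results not called with all libraries, except the granulocyte list between intMo and cMo. Between pMo and intMo, Itgam was at -0.01 and Hes1 at -0.04 with upper quartile scaling, Hes1 at 0 with the filter at 1 CPM, and Col1a2 at 0.02 with the replicate block (log2). On leaving out 1 library, Itgam ranged from -0.03 to 0.13, Hes1 from -0.31 to 0.40, Col1a2 from -0.64 to 0.72 and Csf1r from -0.26 to 0.25. S100a9 ranged from -0.80 to 1.04 between intMo and cMo and from -1.48 to 0.33 between pMo and cMo. With libraries 1 and 2 alone, S100a9 was called higher at 1.58 and 0.81 in those contrasts, while Csf1r at 0.16 and Col1a2 at 0.28 between pMo and intMo were not called. Camera's adjusted p between pMo and intMo ranged on leaving out 1 library from 0.019 to 0.824 for the conventional monocyte list, 0.109 to 0.812 for interferon-stimulated genes and 0.24 to 0.974 for lysosome genes. It ranged from 0.0112 to 0.801 for immediate early genes, 0.0678 to 0.713 for mitochondrial genes and 0.0542 to 0.894 for stromal genes, and between pMo and cMo from 0.641 to 0.989 for dendritic cell genes. With libraries 1 and 2 alone it was 0.117 for the granulocyte list between intMo and cMo, 0.196 for stromal and 0.215 for mitochondrial genes between pMo and intMo, and 0.819 for dendritic cell genes between pMo and cMo, each with the other direction. The cause was not tested. Depth limits genes with few counts, such as Cxcl1, Cd209a and, between pMo and cMo, Prss34, for which bounds or counting intervals stand in place of fitted folds.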

Other observations

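The patterns weighed and the tests of explanations in this part were chosen after the result was seen, while the contrasts and the leaving out of libraries were fixed before. Some genes did not run evenly from cMo through intMo to pMo. Slc40a1, the iron exporter ferroportin, had 36.7 ± 14.6, 706 ± 292 and 142 ± 51 CPM in cMo, intMo and pMo, with log2 changes of 4.27 ± 0.45 and then -2.31 ± 0.41 (SE, edgeR adjusted p = 0.0145 for the fall). Bank1, a scaffold of B cell signalling, had 12.4 ± 3.1, 123 ± 11.5 and 33.4 ± 1.86 CPM (log2 3.31 ± 0.19 and -1.88 ± 0.18). Siglech had 4.16 ± 0.707, 35 ± 1.57 and 0.649 ± 0.295 CPM (log2 3.07 ± 0.26 and -5.75 ± 0.31). Ccr1 rose by 1.39 ± 0.17 and fell by 1.22 ± 0.16, and Trf, the iron carrier transferrin, rose by 2.62 ± 0.28 and fell by 1.24 ± 0.27 (edgeR adjusted p = 0.0315 for the fall). The fall of Slc40a1 was not called without pMo 1 or pMo 2 (up to 0.0777), and that of Trf without cMo 1 or any pMo library (up to 0.138) or with the replicate block (0.0578). In all 132 genes rose and then fell, 76 fell and then rose, 139 rose in both steps and 33 fell in both. Independent steps would give 33.3, 48.3, 64.7 and 24.8. With libraries 1 and 2 alone the counts were 467, 188, 374 and 490. Both steps share the 3 intMo libraries undivided, so part of the excess may come from them. Siglech and Clec9a peaked and are dendritic cell genes, and such cells mixed into intMo were not tested for.

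The count over any subset, 4644 genes, was reached by 1 of 100 splits, the real one. Others with cMo kept whole gave 1894 to 3223, and the rest up to 153. This shows that cMo differs. Splits ignored replicate numbers, and too few kept cMo whole to exclude chance between intMo and pMo. For the pairwise counts of 3433, 701 and 4650 genes, 1 of 10 splits, the real one, was as large in each, the highest other was 0 by edgeR (up to 1297, 1246 and 920 genes at an unadjusted p under 0.05, against 5285, 2619 and 6099), and 10 splits are too few for a share under 0.05.

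Nr4a1 was higher in pMo than in intMo, and it is both a regulator of patrolling monocytes and an immediate early gene. RNA of stromal cells as the source is argued against, since the log2 change of Nr4a1 lay 1.44 above the mean of 15 stromal cell genes (-0.21, SD 0.21). A response to handling of the cells may contribute and cannot be told apart from a difference between the subsets, since Nr4a1 lay 1.09 SD above the mean of the immediate early and heat shock genes (0.16, SD 0.97), which spread widely. In the libraries numbered 0 Nr4a1 exceeded the other two by 0.42 in intMo and 0.28 in pMo, and those genes by 1.52 ± 1.30 and 1.23 ± 1.43. A difference between the subsets remains open as well.

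Nrarp and Hes1, which Notch signalling induces, were higher in intMo and pMo than in cMo, as were stromal cell genes. If their RNA came from stromal cells, they would follow the stromal genes in the libraries numbered 0, where those exceeded the other two by 1.13 ± 0.51 on average (1.47 ± 0.58 in intMo and 0.79 ± 0.49 in pMo). Nrarp did not, with a mean of -1.89 (-3.64 in intMo and -0.14 in pMo), but the difference was carried by intMo library 0 and lay within 2 SD in pMo. Stromal RNA as the source of Nrarp therefore cannot be told apart from RNA of the monocytes. Hes1 did, with a mean of 0.88 (0.92 and 0.85), so stromal RNA may account for Hes1. Notch signalling in the monocytes was not tested apart from this and remains open for both genes.

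MHC class II genes were higher in the libraries numbered 0 of intMo (0.89 ± 0.67, 13 of 14 genes) and pMo (1.10 ± 1.01, 11 of 14) than in the other two. Fewer granulocytes in these libraries are argued against as the whole cause, since patrolling monocyte genes did not gain (mean -0.08, with -0.21 ± 0.55 in intMo and 0.05 ± 0.49 in pMo). Stromal genes rose in the same libraries (1.47 ± 0.58 and 0.79 ± 0.49), with a summed gain of 601 CPM against 10861 CPM for MHC class II genes in intMo and of 263 against 7131 CPM in pMo. At the lowest ratio of MHC class II to stromal CPM in any intMo or pMo library, 10.6, stromal cells can supply up to 0.59 of the gain in intMo and 0.39 in pMo, so their RNA cannot be told apart from that of the monocytes, as their MHC class II content was not measured. In cMo library 0 all 14 genes were lower, with a median of -1.13, yet a batch that acts differently on each subset cannot be told apart from differences between cultures, since each subset has 1 library of that number and the labels give no batch. No biological explanation was tested, as the labels name none for the replicate numbers.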
